A study of Mus musculus with 26 samples.

How the data were processed

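Small RNA was sequenced from the CA1 region of the hippocampus of mice, dissected under a microscope and frozen. Per the labels' protocols, libraries were made with the TruSeq Small RNA kit and sequenced on a HiSeq2000 as single reads of 50 bp. The submitters' processing notes name FastQC 0.11.5 and the mm10 genome build. The aligner, the miRNA annotation and the counting settings are not given in the sources used here.

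There were 26 libraries in 3 groups, taken from the genotype and agent labels. The groups were 9 wild type littermates on vehicle, 7 transgenic mice on vehicle and 10 transgenic mice on Vorinostat. Per the labels' protocols, the transgenic mice were assigned to Vorinostat or vehicle at random, treatment ran for 4 weeks from an age of 2 months, and both sexes were used. The sex of each animal is not given in the sources used here. The labels do not state that each library is a separate animal, so p-values measure the spread between libraries.

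The authors deposited raw counts per mature miRNA for all 26 libraries, in 1915 table entries, of which 526 had no read. Among entries with reads, 144 held the same counts as another entry in every library, in 50 patterns that took 0.259% of all counts. Values of such near-identical miRNAs (for example miR-486a-5p and miR-486b-5p) are one measurement and cannot be assigned to a single locus. miRNAs of a family that differ by few bases, such as those of let-7, are uncertain in the same way.

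The authors also deposited a table of normalized values for 674 miRNAs on a log2 scale. How they were made is not given in the sources used here. Their size was close to that of log2 CPM (defined below) for abundant miRNAs, and they differed from it by an amount that varied with miRNA and library. Another deposited table gives, per the file headers, a membership of each of these miRNAs in 5 co-expression modules, from -1 to 1, beside p-values of membership that were not used here. The modules were built by the authors, so they are not independent of these libraries.

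Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Trimmed-mean (TMM) factors were used, and miRNAs were filtered with filterByExpr at its settings of a minimum count of 10 and a total of 15, which left 605. The minimum count applies at the median depth and in about as many libraries as the smallest group holds, so single libraries can have 0 counts. One model held all 3 groups and no covariate, and 3 contrasts were taken from it, all two-sided. Benjamini-Hochberg adjusted p-values under 0.05 counted as passing. CPM values are counts divided by the library total times the TMM factor, on a scale of 1e6. Fold changes are edgeR log2 values with their standard errors (SE).

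Lists of miRNAs were fixed before the data were examined: 22 lists for cell types, neighbouring or other tissues, pathways, families and genomic clusters, of which 21 had at least 3 members among the tested miRNAs. They were compared with the other miRNAs by camera of limma 3.58.1 on voom values with a preset correlation of 0.01 between members, and adjusted over the 21 lists. The same test with an estimated correlation, and fry, were alternatives. Each list was also adjusted over the list alone. Module scores were the first principal component of the scaled log2 CPM of a module's members, compared between groups by exact permutation tests, two-sided, and adjusted over the 5 modules.

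The transgenic vehicle libraries enter the genotype comparison and the Vorinostat comparison with opposite signs, which by itself gives a negative relation between both. The covariance of the 2 effects across miRNAs was therefore computed with different transgenic vehicle libraries on each side, averaged over the 35 divisions of the 7 libraries into 3 and 4, and compared with 100 relabellings of the transgenic libraries. These relabellings do not keep the pairs described below, so all 128 exchanges within pairs were added as an alternative after seeing the data.

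The miRNAs named were chosen by a rule fixed before the data were examined: those past the threshold, and where fewer than 10 passed in a comparison, the 5 higher and 5 lower miRNAs with the smallest unadjusted p. Per list, up to 4 members past the threshold or the 2 most abundant were named, and a fixed set of miRNAs known from brain, heart, blood and inflammation was always included. Of that set miR-208a-3p, with 2 reads in all libraries together, and miR-223-3p, with 138 reads, were below the filter and not tested. The rule gave 69 miRNAs. miR-96-5p and the miRNAs led by the authors' values or by the deviation of single libraries were chosen after their values were seen.

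Genomic positions were taken from the GENCODE annotation of GRCm38, the assembly that mm10 denotes, by the name of the hairpin gene.

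Alternatives fixed before the data were examined were other scaling factors (RLE, library totals only, upper quartile), other filters (none, a mean of at least 10 CPM), DESeq2 1.42.0, limma voom with and without library weights, a robust fit, fits of only the groups compared, the replicate number as a block, the log2 library total or 1 surrogate variable (sva 3.50.0) as a covariate, limma on the authors' normalized values, and leaving out each library in turn. Chosen after seeing the data were fits without wild type vehicle replicate 1 and Vorinostat replicate 8, fits with the sequencing lane as a covariate or within a lane, collapsed duplicate entries, the first principal component, 2 or 8 surrogate variables, the replicate block or the lane without wild type vehicle replicate 1, and 8 or 9 library components as covariates.

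Those components were recovered from the difference between the authors' values and log2 CPM over 62 miRNAs with at least 500 counts in every library. The difference had 9 components over libraries above a floor, with a singular value of 0.586 for the ninth and 0.0116 for the tenth.

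Replicate numbers come from the labels, which do not say what they mark. Deviations from the group means of same-numbered transgenic vehicle and Vorinostat libraries correlated in 7 of 7 pairs (0.265 to 0.599), so the numbers were taken to pair these libraries. The mean correlation was 0.429 for the same number and 0.142 for other numbers in the same lane, and 6 of the 7 pairs shared a lane. Only 5 of these 14 libraries correlated best with their own number, so the pairing is an assumption. The lane (L001 or L002) is in the column names of the counts, with 13 libraries in each. L001 held 6 wild type vehicle, 3 transgenic vehicle and 4 Vorinostat libraries, and L002 held 3, 4 and 6. Group and lane are therefore partly confounded, and values within a lane rest on 3 to 6 libraries per group.

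The tests were run first on simulated counts with the means, depths and dispersions of the 605 miRNAs. For the genotype comparison the edgeR test recovered 34.6% of simulated changes of 1.5-fold, 66.1% of 2-fold and 98.4% of 4-fold changes. For the Vorinostat comparison it recovered 27.1%, 67.2% and 100%. It called 0 miRNAs when none was changed, and of 132 calls in the genotype run with changes 5 were of unchanged miRNAs (0 of 130 for Vorinostat). With 1 list, the miR-181 family, shifted by 1 log2 unit camera called that list and 1 other. The hypoxia and ischemia list and the plasticity and activity list share members with that family, and which list was the other was not recorded. A called list can therefore be a false one or one that shares members with a changed list, and this run does not separate these. The miRNAs were simulated independently of each other and without a library of outlying profile, so these rates may not carry over. Other groupings of the real libraries gave up to 229 miRNAs in edgeR and up to 6 lists in camera. Depth per library ranged from 0.585 to 24.8 mega-counts, and reads are not independent molecules. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 69.3 over 102 pairs.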

Results

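The series asked how small RNAs in the brain relate to heart failure and memory impairment, and what the histone deacetylase inhibitor Vorinostat (also called SAHA) does to them. The transgenic animals were CamkdeltaC mice, a model in which a form of calcium/calmodulin-dependent kinase II delta drives heart failure. miRNAs were counted in CA1, a field of the hippocampus needed for memory, in 9 wild type vehicle, 7 transgenic vehicle and 10 transgenic Vorinostat libraries. The mice were 3 months old at the end of 4 weeks of treatment in drinking water.

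Total miRNA counts, in mega-counts (M), were 10.8 ± 4.68 M (SD, n = 9) in wild type vehicle, with a range from 0.585 to 17.6 M. They were 13.2 ± 7.57 M (SD, n = 7) in transgenic vehicle, from 6.02 to 24.8 M, and 11.1 ± 3.49 M (SD, n = 10) with Vorinostat, from 3.89 to 15.7 M. Mean depth did not differ beyond the spread between libraries (exact permutation test, adjusted p = 0.677 for genotype, 0.677 for Vorinostat and 0.903 for Vorinostat against wild type). The neuronal miRNA miR-128-3p took 22.7 ± 3.49% of counts (SD over all 26 libraries), followed by miR-9-5p with 12.7 ± 2.72%, miR-99a-5p with 7.15 ± 1.30%, miR-26a-5p with 6.15 ± 1.71% and miR-127-3p with 4.99 ± 3.08%.

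Wild type vehicle replicate 1 stood apart. It held 0.585 M counts, its most abundant miRNA was miR-127-3p at 18.3% rather than miR-128-3p at 11.98%, and it scored -65.2 on the first principal component, which held 59.2% of the variance. Vorinostat replicate 8 came next with -25.9, and the other libraries lay between -12.4 and 13.99. The log10 of the total counts correlated with this component (Pearson r = 0.813, permutation p = 7e-04; Spearman rho = 0.29, permutation p = 0.151; n = 26). Without these 2 libraries r was 0.157, so the relation rested on them. Within lanes r was 0.908 (L001, which holds wild type vehicle replicate 1) and 0.448 (L002, which holds Vorinostat replicate 8). Each value thus keeps 1 of these 2 libraries and does not show the relation without them.

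**Figure D1:**
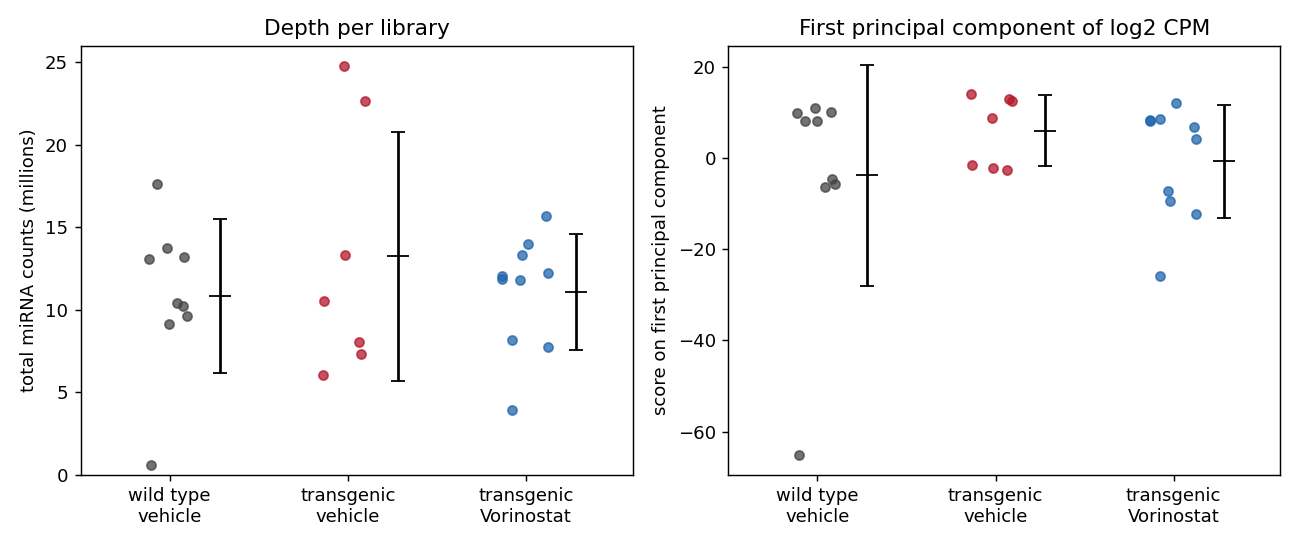
Total miRNA counts per library (left, M) and score on the first principal component of log2 CPM (right), one point per library, with the mean and SD of each group as bars. Wild type vehicle replicate 1 lies lowest in both plots, at 0.585 M counts and a score of -65.2.

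The genotype comparison asked how CA1 miRNAs differ between transgenic and wild type mice on vehicle. miR-182-5p and miR-183-5p, processed from a cluster listed here for another region (sensory and thalamic), averaged 46.0 ± 10.04 and 38.5 ± 16.97 CPM in transgenic vehicle (SD, n = 7) against 145 ± 255 and 98.5 ± 152 CPM in wild type vehicle (SD, n = 9). The log2 difference was -1.59 (SE 0.59) for miR-182-5p and -1.29 (SE 0.55) for miR-183-5p. miR-219a-5p, which promotes oligodendrocyte maturation, averaged 4.55 ± 1.29 CPM against 2.14 ± 1.53 CPM, a log2 difference of 0.95 (SE 0.39), and lay above the wild type mean in 7 of 7 transgenic libraries. miR-181a-5p, abundant in neurons, averaged 12909 ± 1726 CPM against 11237 ± 1396 CPM, a log2 difference of 0.20 (SE 0.11). None of these passed, with an edgeR adjusted p of 0.98 for each. The far more abundant miR-219a-2-3p, the other arm of the Mir219a-2 hairpin, averaged 968 ± 214 CPM in transgenic vehicle (SD, n = 7) against 908 ± 328 CPM in wild type vehicle (SD, n = 9). It lay above the wild type mean in 5 of 7 transgenic libraries.

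Of 605 miRNAs, 0 passed in edgeR, and 13 had an unadjusted p under 0.05. DESeq2 also called 0 (18 unadjusted) and limma voom 0 (7 unadjusted). Each of these unadjusted counts is below the share of 0.05 expected with no difference. The other miRNAs with the smallest p were miR-143-5p (log2 difference 0.77, SE 0.34), miR-500-3p (0.51, SE 0.24) and miR-190b-5p (0.75, SE 0.36) on the higher side. On the lower side they were miR-151-3p (-1.91, SE 0.73), miR-148a-3p (-1.41, SE 0.59) and miR-1981-5p (-1.21, SE 0.53). The lower values rested on wild type vehicle replicate 1. Without it the log2 difference was -0.41 (SE 0.34) for miR-182-5p, -0.35 (SE 0.37) for miR-183-5p, -0.14 (SE 0.42) for miR-151-3p, -0.18 (SE 0.36) for miR-148a-3p and -0.27 (SE 0.36) for miR-1981-5p. Within lane L001, which holds that library, miR-182-5p differed by -2.01 and miR-183-5p by -1.87. Within L002 the values were -0.26 and 0.04, and 0 miRNAs passed in either lane (23 and 8 unadjusted). For miR-219a-5p the values were 0.83 in L001 and 1.32 in L002.

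Among the preset lists, the miR-181 family passed as higher in transgenic vehicle with the preset correlation (camera adjusted p = 0.0107), and not with an estimated correlation (adjusted p = 0.586). All 7 members had a higher mean, with a median log2 difference of 0.21, among them miR-181a-5p (0.20), miR-181b-5p (0.14, SE 0.12) and miR-181c-5p (0.21, SE 0.19), and none passed singly. The call was lost without wild type vehicle replicate 1 (adjusted p = 0.0590), without wild type vehicle replicate 5 (0.0546) and with lane as a covariate (0.0601). The unadjusted camera p within lanes was 0.00302 in L001 and 0.875 in L002. Adjusted p-values over all alternatives ran from 5.28e-04 to 0.994.

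The other 20 lists did not pass in the genotype comparison. The miR-183 cluster had a median of -1.29 over 3 members (adjusted p = 0.0653). Adjusted over the list alone, 2 of its members passed in edgeR, miR-182-5p and miR-183-5p, against 0 over all miRNAs; the median was -0.38 without wild type vehicle replicate 1 and Vorinostat replicate 8. In every other list 0 members passed, also when adjusted over the list alone. The hypoxia and ischemia list, which shares miR-181a and miR-181b with the miR-181 family, had a median of 0.20 over 17 members (adjusted p = 0.0521). The oligodendrocyte list had a median of 0.14 over 12 (0.0653) and the miR-29 family, known to repress collagen genes, 0.33 over 7 (0.0653). The astrocyte and glial progenitor list had a median of 0.17 over 16 members, the endothelium and vessel wall list 0.23 over 13, and the miR-34 and miR-449 family 0.33 over 5, each with an adjusted p of 0.183. The 5 tested members of the last list are all of miR-34, and no miR-449 was tested. Heart and skeletal muscle miRNAs had a median of 0.24 over 5 members (0.362), with miR-1a-3p at 0.24 (SE 0.19) and miR-133a-3p at 0.64 (SE 0.45). The median was 0.08 for 16 inflammation miRNAs (0.362), among them miR-146a-5p (0.10, SE 0.23), miR-155-5p (-0.22, SE 0.52) and miR-21a-5p (0.25, SE 0.21).

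For 31 neuron-enriched miRNAs the median was 0.06 (adjusted p = 0.538), with miR-128-3p at 0.01 (SE 0.14), miR-9-5p at 0.19 (SE 0.16) and miR-124-3p at 0.24 (SE 0.31). It was 0.08 for 42 plasticity and activity miRNAs (0.411) and -0.01 for the 4 members of the miR-132 and miR-212 cluster (0.728), which responds to neuronal activity. The remaining medians were 0.08 for 7 erythrocyte miRNAs (0.851), 0.17 for 12 choroid plexus and ependyma miRNAs (0.460) and 0.22 for the miR-17 and paralog clusters (0.728). Median, mean and test direction differed in sign for 5 lists. These were microglia and leukocyte (median 0.06, mean -0.03, direction down, adjusted p = 0.944), let-7 and miR-98 (-0.01, 0.05, up, 0.944), miR-30 (0.16, -0.02, up, 0.380), the Dlk1-Dio3 imprinted cluster (0.02, -0.03, down, 0.944) and the Sfmbt2 intron cluster (0.14, 0.07, down, 0.428).

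The Vorinostat comparison asked what the drug did to CA1 miRNAs of transgenic mice. With Vorinostat 3 lists passed in camera with the preset correlation, the miR-183 cluster as higher and the miR-34 and miR-449 family and the miR-29 family as lower, and no single member passed. With an estimated correlation none of the 3 calls held (adjusted p = 0.397, 0.397 and 0.484). In the miR-183 cluster miR-182-5p averaged 112 ± 72.6 CPM (SD, n = 10) against 46.0 ± 10.04 CPM with vehicle (SD, n = 7), and miR-183-5p 82.7 ± 60.6 against 38.5 ± 16.97 CPM. Each lay above the vehicle mean in 10 of 10 libraries, with log2 differences of 1.28 (SE 0.57) and 1.10 (SE 0.53). miR-96-5p, the remaining member, differed by 0.80 (SE 0.44), lay above the vehicle mean in 6 of 10 libraries and was highest in Vorinostat replicate 2. In the miR-34 and miR-449 family, which contains targets of p53, all 5 tested members were lower, with miR-34b-3p at 4.43 ± 2.15 against 7.54 ± 1.95 CPM (log2 difference -0.75, SE 0.28) and miR-34c-5p at 55.7 ± 12.3 against 79.2 ± 42.6 CPM (-0.51, SE 0.28). No miR-449 was among the tested members of this family, so its call concerns miR-34 only. All of its members except miR-34a-5p are also in the preset choroid plexus and ependyma list, which stands for neighbouring tissue. In the miR-29 family 5 of 7 members were lower, led by miR-29b-3p at 988 ± 357 against 1740 ± 1165 CPM (-0.82, SE 0.32).

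The camera adjusted p was 0.00882 for the miR-183 cluster (3 of 3 members higher, median 1.10), 0.0167 for the miR-34 and miR-449 family (5 of 5 lower, median -0.51) and 0.0441 for the miR-29 family (5 of 7 lower, median -0.44). With the replicate number as a block over all 26 libraries, the camera adjusted p was 0.0771 for each. That block also ties in the wild type libraries, whose numbers were not taken to pair, so it is not a test of the 7 pairs alone. Within the 7 pairs, a comparison chosen after seeing the data, miR-182-5p was higher with Vorinostat in 7 (mean log2 difference 1.34, SD 0.84), miR-183-5p in 6 (1.20, SD 1.08) and miR-96-5p in 5 (0.44, SD 1.13). The exact unadjusted p was 0.0156, 0.0312 and 0.375, and with the block in edgeR the adjusted p was 0.790, 0.790 and 0.808. For the miR-183 cluster the unadjusted camera p was 1.34e-04 in lane L001 and 0.00657 in L002, for the miR-34 and miR-449 family 6.64e-05 and 0.129, and for the miR-29 family 0.00987 and 0.0415. Adjusted over the lists, the miR-183 and miR-34 calls were lost in L002 (camera adjusted p = 0.082 and 0.540). The miR-29 call was lost in both lanes (0.0504 in L001 and 0.290 in L002). No library, left out alone, ended the call of the miR-183 cluster (adjusted p from 7.15e-05 to 0.0476). Without transgenic vehicle replicate 9 or 10 the miR-34 and miR-449 call ended (0.127 and 0.0693), and the miR-29 call ended without any of 8 single libraries, most so without transgenic vehicle replicate 5 (0.161). Over all alternatives the adjusted p ran from 7.15e-05 to 0.397 for the miR-183 cluster, from 0.00139 to 0.540 for the miR-34 and miR-449 family and from 0.0220 to 0.484 for the miR-29 family.

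**Figure D2:**
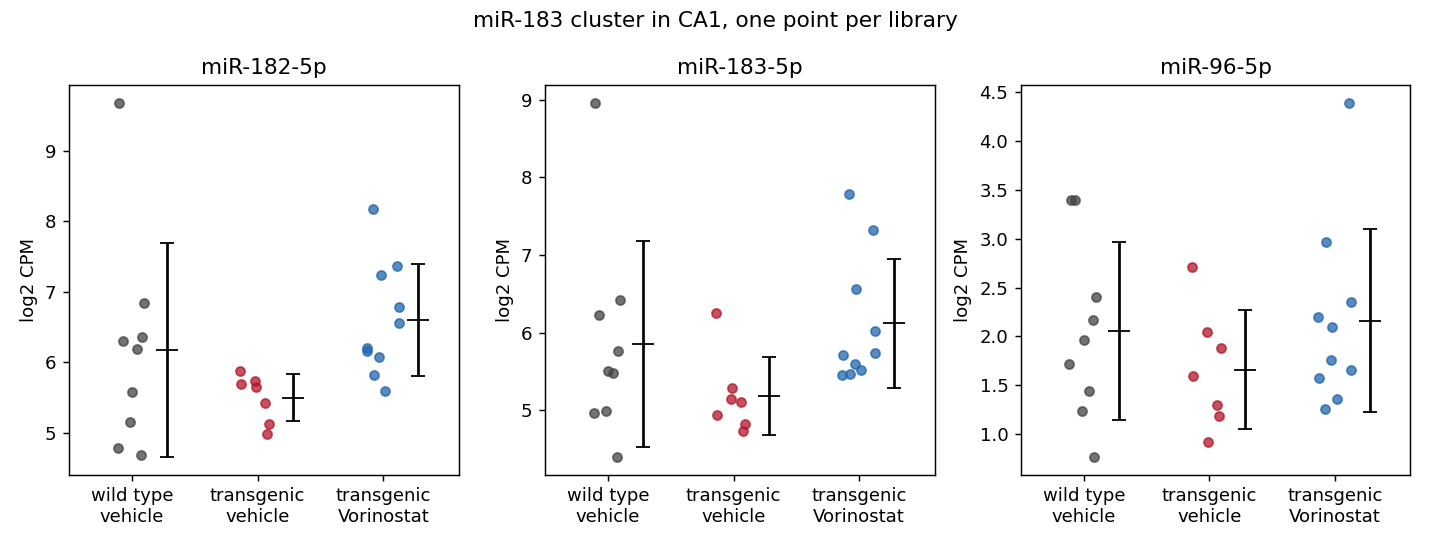
log2 CPM of miR-182-5p, miR-183-5p and miR-96-5p in each library of the 3 groups, with the mean and SD of each group as bars. All 10 Vorinostat libraries lie above the transgenic vehicle mean for miR-182-5p and miR-183-5p, and wild type vehicle replicate 1 lies highest for both, at 9.68 and 8.96.

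Of 605 miRNAs, 0 passed in edgeR for Vorinostat against vehicle in transgenic mice (smallest adjusted p = 0.836), and 21 had an unadjusted p under 0.05. DESeq2 called 0 (26 unadjusted, smallest adjusted p = 0.0939) and limma voom 0 (16 unadjusted). Here too each unadjusted count is below the share of 0.05 expected with no difference. The other miRNAs with the smallest p were miR-1306-3p (log2 difference 0.76, SE 0.28), miR-6896-5p (0.85, SE 0.31), miR-881-3p (0.74, SE 0.32) and the Hox-linked miR-10a-5p (0.71, SE 0.32) on the higher side. On the lower side they were miR-500-3p (-0.62, SE 0.23), miR-181c-5p (-0.41, SE 0.19) and miR-879-5p (-0.71, SE 0.33). miR-6896-5p lay above the vehicle mean in 10 of 10 libraries. Within lane L001 the difference was 0.00447 for miR-1306-3p and -0.03 for miR-10a-5p, and within L002 1.18 and 1.02. Without transgenic vehicle replicate 5 the difference was -0.41 for miR-29b-3p and -0.27 for miR-181c-5p. In L001 9 and in L002 24 miRNAs had an unadjusted p under 0.05, and 0 passed in either.

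The remaining 18 lists did not pass in the Vorinostat comparison, and in no list did a member pass when adjusted over the list alone. The astrocyte and glial progenitor list, which shares the miR-29 family, had a median of -0.22 over 16 members (adjusted p = 0.0665), and the miR-132 and miR-212 cluster 0.19 over 4 (0.203). miR-132-3p differed by 0.17 (SE 0.15) and miR-212-3p by -0.09 (SE 0.21). The median was 0.19 for erythrocyte miRNAs (0.378), -0.09 for the miR-181 family (0.378), -0.10 for let-7 and miR-98 (0.327), -0.27 for the miR-17 and paralog clusters (0.327) and -0.17 for endothelium and vessel wall (0.680). It was -0.06 for heart and skeletal muscle (0.680), -0.02 for plasticity and activity miRNAs (0.680), -0.02 for miR-30 (0.954), -0.03 for hypoxia and ischemia (0.954) and -0.16 for the Sfmbt2 intron cluster (0.835). Median, mean and direction differed in sign for neuron-enriched (median -0.03, mean 0.00231, up, adjusted p = 0.680), oligodendrocyte (0.00387, -0.05, down, 0.954), microglia and leukocyte (-0.08, 0.04, down, 0.954), choroid plexus and ependyma (0.05, -0.09, down, 0.680), inflammation (-0.02, 0.00144, up, 0.954) and the Dlk1-Dio3 imprinted cluster (-0.00555, 0.06, up, 0.504). Of the hindbrain list only miR-10a-5p and miR-10b-5p were measured above the filter, so the list was not tested.

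The last comparison set transgenic mice on Vorinostat against wild type mice on vehicle. miR-128-3p, the most abundant miRNA, averaged 260220 ± 52101 CPM (SD, n = 10) against 209580 ± 40302 CPM (SD, n = 9), a log2 difference of 0.31 (SE 0.13). let-7b-5p averaged 4149 ± 628 against 5305 ± 1466 CPM (-0.35, SE 0.14), and lay below the wild type mean in 9 of 10 libraries. The erythroid miR-486a-3p and miR-486b-3p differed by 0.84 (SE 0.31) and 0.76 (SE 0.31), let-7j by 0.28 (SE 0.11) and miR-10b-5p by 1.65 (SE 0.70). On the lower side were miR-188-5p (-0.78, SE 0.30), miR-34b-3p (-0.63, SE 0.27), let-7k (-0.54, SE 0.23) and miR-23b-5p (-0.56, SE 0.25). None passed in edgeR, with an adjusted p of 0.9997 for each. miR-486a-3p is a scarce arm, at 8.13 ± 4.93 CPM with Vorinostat against 4.21 ± 2.07 CPM in wild type vehicle. The abundant arm, where miR-486a-5p and miR-486b-5p are one measurement, averaged 550 ± 178 against 576 ± 372 CPM. The erythrocyte miR-451a averaged 215 ± 80.4 against 202 ± 108 CPM.

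Of 605 miRNAs, 0 passed in edgeR in this comparison and 19 had an unadjusted p under 0.05, with 0 in DESeq2 (29 unadjusted) and 0 in limma voom (23 unadjusted). These unadjusted counts are also below the share of 0.05 expected with no difference. Without Vorinostat replicate 8 the difference of miR-10b-5p was 0.52. Within lane L001 miR-486a-3p differed by -0.16, miR-486b-3p by -0.18, miR-128-3p by 0.00818 and miR-10b-5p by 0.38, and within L002 by 1.11, 0.97, 0.37 and 2.17. Of the 21 lists 0 passed, and the smallest adjusted p, 0.159, was shared by the oligodendrocyte list (median 0.18) and the hypoxia and ischemia list (median 0.12). Median, mean and direction differed in sign for 6 lists. These were plasticity and activity, microglia and leukocyte, choroid plexus and ependyma, the miR-183 cluster, miR-30 and the Sfmbt2 intron cluster. miR-182-5p lay at -0.31 (SE 0.51) against wild type, and at 0.59 (SE 0.28) without wild type vehicle replicate 1 and Vorinostat replicate 8.

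The authors' 5 co-expression modules were compared on log2 CPM. The turquoise module (404 members) and the blue module (197 members) differed between transgenic and wild type vehicle by 0.61 and -0.41 SD of the score (exact permutation test, adjusted p = 0.690 for both, n = 7 and 9). Vorinostat against vehicle gave -0.33 and 0.53 (adjusted p = 0.450 for both by exact permutation). The brown (34 members), yellow (25) and green (14) modules differed by 0.47, 0.22 and -0.47 for genotype and by -0.05, 0.42 and -0.00995 for Vorinostat, and 0 of 5 modules passed in any comparison. The smallest unadjusted p was 0.224, for the yellow module in Vorinostat against wild type. With the replicate number as a block, over 7 pairs, the blue module rose by 0.64 and the turquoise module fell by 0.41 with Vorinostat (exact permutation adjusted p = 0.0391 for both). The unadjusted p of 0.0156 is the smallest that 7 pairs allow.

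Whether Vorinostat moved miRNAs against the genotype difference was tested with separate transgenic vehicle libraries on each side. The covariance of both effects across miRNAs was -0.0642 (correlation -0.328), against a mean of 0.00498 in relabelled libraries (permutation p = 0.129). Against the 128 exchanges of labels within the 7 pairs, a test chosen after seeing the data, the exact p was 0.00781, the smallest possible, with a mean of 0.0331 in the exchanged libraries. The negative value rested on wild type vehicle replicate 1: without it the covariance was 0.00205 (permutation p = 0.812, and 0.172 within pairs). With all transgenic vehicle libraries on both sides the covariance was -0.118 and the correlation -0.738. Relabelling all libraries gave a mean of -0.0923 and -0.510, and relabelling the transgenic libraries alone -0.0662 and -0.522 (permutation p = 0.119).

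The authors' deposited normalized values gave another picture, and how they were adjusted is not given in the sources used here. In limma on these values, 230 of 674 miRNAs were higher and 137 lower in transgenic vehicle than in wild type vehicle. With Vorinostat against vehicle 111 were higher and 251 lower, and against wild type 1 was higher and 5 were lower. In transgenic vehicle, miR-124-3p, the classic neuronal miRNA, was higher by 1.30 (SE 0.28, limma adjusted p = 0.00207), miR-338-3p, an oligodendrocyte miRNA, by 1.66 (SE 0.34, limma adjusted p = 0.00184) and miR-29a-3p by 1.09 (SE 0.26, limma adjusted p = 0.00325). miR-182-5p was lower by a log2 value of -1.14 (SE 0.38) and miR-127-3p by -1.02 (SE 0.23). With Vorinostat each went the other way: miR-124-3p -1.33 (SE 0.27), miR-338-3p -1.57 (SE 0.33), miR-29a-3p -1.14 (SE 0.25), miR-182-5p 1.72 (SE 0.37) and miR-127-3p 1.01 (SE 0.22). In edgeR on the counts miR-124-3p differed by 0.24 (SE 0.31) for genotype and -0.33 (SE 0.30) for Vorinostat, and the other 4 had the same sign as in the authors' values and did not pass.

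By list, 14 of 22 let-7 and miR-98 members passed as higher in transgenic vehicle in the authors' values and 18 passed as lower with Vorinostat. For the Sfmbt2 intron cluster these were 21 and 18 of 35, for the Dlk1-Dio3 imprinted cluster 41 and 41 of 94 (with 24 lower and 18 higher), and for the miR-29 family 4 and 5 of 7. In camera on the same values, with the preset correlation and chosen after seeing the data, the adjusted p for genotype and Vorinostat was 0.0137 and 0.00579 for let-7 and miR-98, 0.0137 and 0.131 for the Sfmbt2 intron cluster, 0.993 and 0.931 for the Dlk1-Dio3 imprinted cluster and 0.238 and 0.128 for the miR-29 family. Since 230 of all 674 miRNAs passed as higher for genotype, counts of members alone do not show a change of a list. The miRNAs past the threshold in Vorinostat against wild type, named after their values were seen, were miR-344e-3p (0.58) on the higher side and miR-34b-3p (-0.67), miR-2137 (-0.63), miR-3963 (-0.75), miR-7220-3p (-0.56) and miR-6918-5p (-0.71) on the lower side. If the authors' step used the group labels, p-values from these values are too small. With the 9 library components recovered from these values as covariates, a fit chosen after seeing the data, edgeR on the counts called 81 miRNAs for genotype, 164 for Vorinostat and 0 against wild type, and with 8 components 89, 176 and 0. Of the miRNAs called in limma on the authors' values and also tested in the counts, 296 of 346 (85.5%) for genotype and 314 of 339 (92.6%) for Vorinostat had the same sign in the plain edgeR fit. Both sets of values come from the same libraries, and the miRNAs were chosen by their calls, so this sharing of sign is not independent support. Higher for genotype and lower with Vorinostat were 196 miRNAs, against 85.7 for independent lists, and 99 were lower and then higher, against 22.6. Both comparisons share the transgenic vehicle libraries, so independence is not the value expected without a reversal. In 50 relabellings of all libraries both means were 0, but the genotype comparison also called 0 there, which leaves nothing to overlap. With the transgenic vehicle libraries divided between both comparisons the means were 35.9 (19.1 for independent lists) and 19.5 (5.56). The authors' values were made before this division, so it does not remove what their step may have added to both parts, and it cannot show a reversal. The modules turquoise and blue differed by 1.38 and -1.65 for genotype (adjusted p = 0.00371 for both, exact permutation) and by -1.49 and 1.45 with Vorinostat (adjusted p = 1.29e-04).

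**Figure D3:**
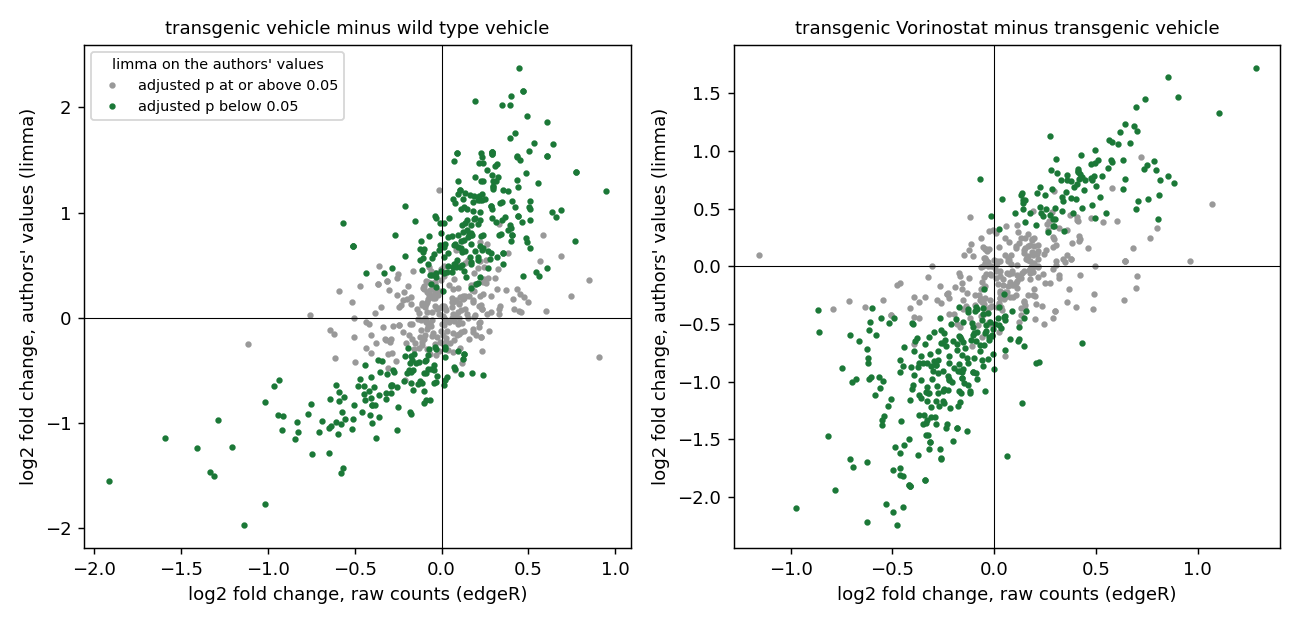
log2 fold change from the raw counts in edgeR (horizontal) against that from the authors' normalized values in limma (vertical), one point per miRNA tested in both, for genotype (left) and Vorinostat (right). Green points have an adjusted p below 0.05 in limma, and no miRNA passed in edgeR.

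In GRCm38 the hairpins of miR-182 (chromosome 6, 30165918 to 30165992), miR-96 (30169446 to 30169551) and miR-183 (30169668 to 30169737) lie within 4 kb on the minus strand, outside annotated genes of that strand. miR-34b (chromosome 9, 51103562 to 51103645) and miR-34c (51103034 to 51103110) are neighbours on the minus strand and also intergenic there. miR-29b-3p can come from Mir29b-1 (chromosome 6, 31063023 to 31063093, minus), in an exon of the long noncoding RNA Gm27019, or Mir29b-2 (chromosome 1, 195037040 to 195037120, plus), in an exon of A330023F24Rik. miR-181a-5p can come from Mir181a-1 (chromosome 1, 137966455 to 137966541, plus), in an exon of A430106G13Rik, or Mir181a-2 (chromosome 2, 38852735 to 38852810, plus), which is intergenic on its strand. miR-219a-5p can come from Mir219a-1 (chromosome 17, 34024983 to 34025092, minus), in an exon of Gm26940, or Mir219a-2 (chromosome 2, 29845631 to 29845727, minus). Counts per mature miRNA do not separate such copies.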

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

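In this part the test of GC content and the counts of other groupings for the lists and the authors' values were set before their results were seen, and the tests of depth, other tissue, surrogate variables, components, choroid plexus, principal component and left-out libraries, and the groupings of the counts, were chosen after. A library was singled out where it lay far from the others of its group (Dixon's criterion): this occurred in 46 of 213 groups of values, where about 1 in 20, or 10.6, arises by chance.

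Of the 46 values, 36 belong to wild type vehicle replicate 1: 0.585 M counts, a first component score of -65.2 and log2 CPM of -2.57, the value of 0 counts, for miR-219a-5p, miR-143-5p, miR-500-3p, miR-486a-3p, miR-486b-3p, miR-188-5p, miR-23b-5p, miR-133a-3p and miR-499-5p. Its log2 CPM was high for miR-182-5p (9.68), miR-183-5p (8.96), miR-151-3p (16), miR-148a-3p (17.6), miR-1981-5p (12), miR-486a-5p and miR-486b-5p (10.6 each), miR-92a-3p (9.37), miR-127-3p (17.8), miR-381-3p (14.5) and miR-451a (8.90). It was low for miR-9-5p (15.6), miR-26a-5p (12.6), miR-24-3p (10.3), miR-29a-3p (10.2), miR-146a-5p (6.23), miR-342-3p (4.65), miR-204-5p (8.01), miR-125b-5p (11.9), miR-30c-5p (8.21), miR-181b-5p (10.6), miR-34a-5p (1.17), miR-124-3p (10.2), miR-138-5p (6.31) and miR-338-3p (4.07). The other values were 8.71 for miR-467a-5p and miR-467b-5p in wild type vehicle replicate 9, and 7.06 for miR-92a-3p in transgenic vehicle replicate 5. In transgenic vehicle replicate 6 they were 6.25 for miR-183-5p, -0.109 for miR-1306-3p and 3.55 for miR-10a-5p. In Vorinostat replicate 8 they were -0.313 for miR-500-3p, 6.56 for miR-10b-5p, 14 for miR-143-3p and 7.82 for miR-138-5p.

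Wild type vehicle replicate 1 differed from the other wild type libraries by 4.71 log2 units for miR-151-3p, 3.79 for miR-148a-3p, -4.16 for miR-30c-5p and -3.32 for miR-26a-5p. Low depth alone is argued against, since with every library thinned to its depth it still lay 3.89 SD of the other libraries away (6.83 before thinning). The GC content of the hairpin arm gave a rho of 0.211 across 577 miRNAs, just above the bound of 0.2 set for no relation, and cannot be told apart from a weak effect. RNA of another region may contribute: the hindbrain miRNAs miR-10a-5p and miR-10b-5p had a median deviation of 2.15, but that rests on 2 miRNAs. Blood RNA stays open as well: the abundant erythrocyte miRNAs miR-451a and miR-486a-5p deviated by 1.55 and 1.79, miR-144-3p and miR-144-5p by -2.17 and -3.64, and scarce members had 0 counts at this depth. The medians of the erythrocyte (-2.17) and muscle (-2.21) lists therefore do not exclude another tissue, and that of choroid plexus was -0.353. No biological explanation was tested for a single library of its group, and library preparation stays open.

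The miR-183 cluster passed as higher with Vorinostat under the preset correlation, and its lower median in transgenic vehicle did not pass (adjusted p = 0.0653, and 0.586 with an estimated correlation). The choroid plexus list changed by 0.0424 times the change of the cluster with Vorinostat (median 0.0468, SD of members 0.441). That list also holds miR-34b and miR-34c, which were lower with Vorinostat, so its median does not exclude choroid plexus in the dissection. The cluster itself was listed for another region (sensory and thalamic). Carry-over of such tissue was not tested and stays open. The first principal component as a covariate left a median of 0.787 (camera p = 1.50e-04), and leaving out wild type vehicle replicate 1 and Vorinostat replicate 8 left 0.879 (camera p = 3.72e-05), both with the preset correlation. The call itself did not hold with an estimated correlation (adjusted p = 0.397) or with the replicate block over all 26 libraries (0.0771). With that block the log2 differences were 1.05 for miR-182-5p, 0.88 for miR-183-5p and 0.35 for miR-96-5p. Neither explanation accounts for the size of the difference, whereas the genotype median went from -1.29 to -0.38. An effect of Vorinostat on the cluster is a hypothesis that stays beside chance: counting the real labels, 65 of 100 groupings gave as many lists as the 1 for genotype (highest other 5) and 15 of 100 as many as the 3 for Vorinostat (highest other 6), so chance cannot be excluded for either count. Among 100 exchanges within the 7 pairs, 16 gave as many lists (highest other 5).

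The authors' normalized values gave 367, 362 and 6 miRNAs where edgeR on the counts gave 0. Counting the real labels, 1, 1 and 2 of 100 groupings gave as many (highest other 226, 0 and 51), so no other grouping did for the first and second comparison, and exchanging labels within the 7 pairs reached 345 for Vorinostat. If the authors' step used the group labels, other groupings would give few calls in any case, so these counts do not separate biology from that step. Removal of library components without counting them stays open: with the 9 components as covariates edgeR called 81 for genotype and 164 for Vorinostat, but the components came from the authors' values, so shared calls were built in. Surrogate variables fitted with knowledge of the groups remain possible: 0 of 99 random groupings treated this way reached the authors' count (highest 155), but the real labels gave only 3, so the trial did not mimic the authors' step and cannot be told apart. The components hold 67.4% of the transgenic vehicle indicator, 51.6% of that of wild type and 31.3% of that of Vorinostat, against 36% by chance, and a biological difference of genotype and drug stays open as well.

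For the counts, 100 of 100 groupings gave 0 or more miRNAs in each of the 3 comparisons (highest other 0, 1 and 229), which says nothing about chance, and 100 of 100 gave as many lists for Vorinostat against wild type (real 0, highest other 6). What the grouping with 229 miRNAs separated was not tested.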

How the results depend on the processing

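Alternatives with a lane, collapsed duplicate entries, a block or lane combined with leaving out a library, differences within pairs, an exchange of labels within pairs, components, more than 1 surrogate variable, the first principal component, the authors' values for lists and for the covariance, or without wild type vehicle replicate 1 and Vorinostat replicate 8 were chosen after seeing the data; the others were planned. The count of 0 miRNAs in edgeR held under 23 of 26 other settings for genotype, 23 of 26 for Vorinostat and 25 of 26 for Vorinostat against wild type, and without each single library (0 to 0). Exceptions were limma on the authors' values (367, 362 and 6), 9 components as covariates (81 for genotype, 164 for Vorinostat) and 8 components (89 and 176). With the replicate number as a block edgeR called 0, 0 and 0, with 29 unadjusted p under 0.05 for Vorinostat. With wild type vehicle replicate 1 also left out, a fit chosen after seeing the data, that number was 94 of 606 (smallest adjusted p = 0.24) and the calls stayed 0. The numbers were not taken to pair wild type with transgenic vehicle (4 of 6 correlations above 0.1, from -0.451) or with Vorinostat libraries (6 of 9, from -0.512), and 2 of 12 and 5 of 18 libraries correlated best with their own number. For transgenic vehicle and Vorinostat, which were taken as paired, it was 5 of 14, so that pairing is uncertain as well.

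The 1 list for genotype became 0 with an estimated correlation, fry, a mean of at least 10 CPM, without the 2 outlying libraries, lane as covariate and lane L002, and 2 in lane L001, the authors' values and with the first component. Leaving out single libraries gave 0 to 5. The 3 lists for Vorinostat became 0 with an estimated correlation, fry, a mean of at least 10 CPM, the replicate block and lane L002, 1 in the authors' values and 5 without the 2 outlying libraries (at a mean of 10 CPM the miR-183 cluster kept under 3 members and was not tested), with 1 to 5 when single libraries were left out. The 0 lists for Vorinostat against wild type became 1 with a mean of at least 10 CPM and in lane L001 and 2 in lane L002 (0 to 1 without single libraries). The 0 modules became 2 in the authors' values for genotype and for Vorinostat and 2 with the replicate block for Vorinostat, and stayed 0 without each single library. The block changed no other call. The covariance of -0.0642 became -0.431 in the authors' values (permutation p = 0.0099, the smallest the relabellings allow, and exact p = 0.00781 with labels exchanged within pairs), with -0.104 to 0.00205 without single libraries. If the authors' step used the group labels, the p-values from their values are too small, also with separate transgenic vehicle libraries on each side. Against exchanges within pairs the -0.0642 in the counts had an exact p of 0.00781, from 0.00781 to 0.172 without single libraries. It passed without 25 of 26 and not without wild type vehicle replicate 1 (0.172). The causes of these shifts were not tested.

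Library totals alone shifted the median of all miRNAs to -0.14 for Vorinostat. Of 8905 fold changes of the 69 named miRNAs under alternatives 823 had the other sign, 717 of them of miRNAs whose difference was smaller than its SE. For the 5 higher and 5 lower miRNAs of each comparison it was 7 of 1282. Reversed and called were 5, all in limma on the authors' values: miR-143-3p (-0.56 against 0.03) and miR-132-5p (0.43 against -0.03) for genotype, and miR-24-3p (-0.44 against 0.05), let-7f-5p (-0.24 against 0.05) and miR-499-5p (-0.84 against 0.21) for Vorinostat. Depth limits low miRNAs: miR-190b-5p averaged 0.534 CPM in wild type vehicle, under 1 read in its shallowest library.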

Other observations

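The tests in this part were chosen after the values were seen. In wild type vehicle replicate 1 miR-182-5p and miR-183-5p were higher by 3.95 and 3.50 log2 units than the mean of the other wild type libraries. miR-96-5p of the same cluster was higher by 1.51, but its log2 CPM of 3.40 was the same in wild type vehicle replicate 4. Within the Dlk1-Dio3 imprinted cluster miR-127-3p lay at 2.57 and miR-434-3p at -3.13, with a median of -1.23 over the cluster. The passenger strand miR-9-3p lay at -3.69, miR-221-3p at -3, and miR-708-3p and miR-129-5p at 2.92 and 2.70.

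With the 9 components that separate the authors' values from log2 CPM as covariates, edgeR fold changes were larger in size than in the plain fit for 539 of 605 miRNAs for genotype (median 0.89 against 0.19), 532 for Vorinostat (0.79 against 0.23) and 338 for Vorinostat against wild type (0.17 against 0.16). The median SE was larger as well, at 0.55 against 0.31, 0.45 against 0.30 and 0.34 against 0.29. Among the miRNAs with the smallest p in that fit, the log2 difference of miR-15a-5p was 3.01 (SE 0.75) for genotype and -3.08 (SE 0.59) for Vorinostat, against 0.60 (SE 0.56) and -0.97 (SE 0.54) in the counts. For miR-184-3p the genotype value was -4.07 (SE 0.95) against -1.14 (SE 0.72), and for miR-679-5p -3.52 (SE 0.87) against -1.02 (SE 0.62), followed by 3.08 (SE 0.71) and 0.85 (SE 0.59) for Vorinostat.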
